A study of Mus musculus with 29 samples.

How the data were processed

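The series measured RNA in megakaryocyte-erythrocyte progenitors (MEPs), the blood progenitors that give rise to platelets and red cells, in 29 mouse samples of 6 genotypes. Per the labels, all samples carried the SclCre transgene (also written ScleCre) and were Ezh2 +/+, Ezh2 +/- or Ezh2 -/-, without or with JAK2 V617F. The groups without V617F held 5 Ezh2 +/+ samples (2 male, 3 female), 4 Ezh2 +/- samples (2 male, 2 female) and 4 Ezh2 -/- samples (1 male, 3 female). The groups with V617F held 4 Ezh2 +/+ samples (1 male, 3 female), 6 Ezh2 +/- samples and 6 Ezh2 -/- samples, and the latter 12 were all female. Each sample's group, sex and replicate number came from its title and characteristics. The labels say only "replicate", so the p-values measure the spread between these samples. The mice's ages, the sorting gates, the sequencing dates and the part of Ezh2 that the deletion removes are not given in the sources used here.

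Per the labels' protocols, RNA came from 230,000 sorted MEPs per sample, was extracted with Trizol-LS and was checked on a Bioanalyzer Pico chip, and libraries followed a standard Illumina protocol. Per the submitters' processing notes, reads were aligned to mouse genome build mm9 with STAR. The STAR version, the read length, the strand setting, the annotation and the counting program are not given in the sources used here. The deposited values are counts, 1 whole number per gene and sample for 18834 Entrez gene identifiers. Gene symbols came from a RefSeq gene table of assembly GRCm38.p6 matched on the Entrez identifier. It was used for names and for chromosome assignment in a check of the sex labels, and no coordinates were taken from it. It named 18772 of the genes, and the other 62 held 0.88 to 2.68% of a library's counts and stayed in the fit. Among the tested genes, 18 had counts identical in every library to those of another gene and formed 9 such sets (among them Hba-a1 with Hba-a2 and Hbb-b2 with Hbb-bt), so reads of these pairs were not told apart.

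Total counts ranged from 31.6 to 59.4 M per library (median 44.6 M), and 15015 to 16387 genes had at least 1 count. A floor of 3 counts corresponds to 0.0505 to 0.095 CPM (counts scaled to library size) in a single library. The floors cover counting error only. No pair of replicates was a duplicate library, since the lowest chi-square per degree of freedom between replicates of a group was 4.9.

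Genes were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3 (minimum count 10, minimum total 15), which left 13928 genes, and libraries were scaled by TMM (factors 0.95 to 1.093). A single quasi-likelihood model with robust dispersion was fitted to all 29 libraries, with a term for each genotype group and a term for the labelled sex. It had 22 residual degrees of freedom, a common dispersion of 0.0326 and a biological coefficient of variation of 18.1%. The first 3 principal components of log2 CPM (prior count 2) held 42.1, 17.8 and 15% of the variance. There were 9 comparisons: Ezh2 -/- and Ezh2 +/- against Ezh2 +/+ without V617F, the same with V617F, V617F against none in each Ezh2 genotype, and the interaction of V617F with Ezh2 -/- and with Ezh2 +/-. All tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as higher or lower. Standard errors were taken from the fold change and its F statistic.

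The named genes followed a rule. In each comparison they were the genes past the threshold with a mean log2 CPM of at least 2, no overlap between the libraries of both groups and the largest absolute fold changes, 10 in each direction in the 4 main comparisons and 5 in the others. The overlap condition was dropped for interactions. Ezh2, Jak2 and up to 4 members of each gene list per direction, those with the lowest adjusted p, were added. Some genes that the rule names are withheld and not reported here.

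There were 24 gene lists, of which 22 were tested: PRC2 subunits, PRC1 subunits, developmental regulators classically under PRC2, Hox genes, fetal-type genes, erythroid, heme biosynthesis, megakaryocyte and platelet, granulocyte, monocyte with macrophage and dendritic, B cell, T and NK cell, mast cell with basophil and eosinophil, stem and multipotent progenitor, JAK-STAT5 target, interferon-stimulated, inflammatory and profibrotic mediators, cell cycle, p53 target, immediate early and stress, cytosolic ribosomal protein, and stromal and endothelial genes. The mitochondrially encoded list could not be tested because 0 of its 13 symbols matched an identifier in the files, and the sex label check list served only to check the labels. The lists held 613 genes present in the files. They were compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 22 lists. The number of members past the threshold is given over all genes and adjusted over the list alone.

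The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were a fit without the sex term, DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, female libraries only, only the groups compared, the replicate number as a block, each library left out in turn, and for the lists the fry test. Chosen after seeing the data were a fit without control replicate 5 and Ezh2 +/- replicates 2 and 5, which stand apart in Cd34, and a fit with the granulocyte, T and NK cell and stem list scores as covariates. A fit without V617F replicate 1, whose sex label does not match its Xist level, was added for the same reason and coincides with leaving that library out.

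The pipeline was tested on simulated data in which 100 genes were changed by a log2 of 1 and 100 by a log2 of 2. It recovered 62 to 82 of the smaller changes and 71 to 96 of the larger ones, and called 4 to 10 unchanged genes, depending on the comparison.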

Results

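Gene counts were measured by RNA-seq in sorted megakaryocyte-erythrocyte progenitors (MEPs) of 6 mouse genotypes. Without JAK2 V617F these were Ezh2 +/+ (control, n = 5), Ezh2 +/- (n = 4) and Ezh2 -/- (n = 4). With V617F they were Ezh2 +/+ (n = 4), Ezh2 +/- (n = 6) and Ezh2 -/- (n = 6). EZH2 is the histone methyltransferase of the Polycomb repressive complex PRC2, and JAK2 V617F is the activating kinase mutation of the myeloproliferative neoplasms. Libraries held 31.6 to 59.4 M counts, and 13928 genes were tested. Levels are mean CPM (counts scaled to library size) ± SD over libraries, changes are log2 fold changes ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For the genes named for the size of their change, apart from those of the interactions, every library of one group lay above every library of the other.

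Ezh2 RNA followed the labelled genotype. It measured 303 ± 20 CPM in controls (n = 5), 192.5 ± 4.28 CPM in Ezh2 +/- (n = 4) and 73.4 ± 5.89 CPM in Ezh2 -/- (n = 4). With V617F the levels were 289 ± 31.2 CPM in Ezh2 +/+ (n = 4), 174 ± 23.2 CPM in Ezh2 +/- (n = 6) and 55 ± 3.1 CPM in Ezh2 -/- (n = 6). The log2 fold change of Ezh2 in Ezh2 -/- was -2.04 ± 0.09 without V617F (edgeR adjusted p = 1.3e-14) and -2.38 ± 0.08 with it (adjusted p = 8.02e-17). In Ezh2 +/- it was -0.66 ± 0.09 (adjusted p = 0.000654) and -0.72 ± 0.08 (adjusted p = 5.41e-05). The call in Ezh2 +/- without V617F was not made among female libraries only (-0.61, adjusted p = 0.79), and the call with V617F was not made in a fit of the compared groups only (-0.69, adjusted p = 0.154). V617F did not change Ezh2 in Ezh2 +/+ (-0.06 ± 0.09, adjusted p = 0.613), and lowered it in Ezh2 -/- (-0.41 ± 0.08, adjusted p = 0.00095). The counts are per gene and the deleted part of Ezh2 is not given in the sources used here, so the reads left in Ezh2 -/- could not be assigned to exons.

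**Figure D1:**
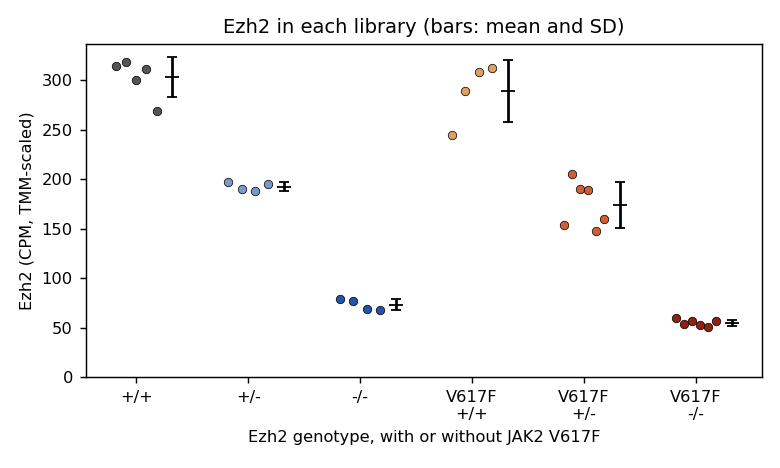
Ezh2 level in CPM (vertical axis) in each library (points) of the 6 genotype groups (horizontal axis), with group mean and SD as a bar. The Ezh2 -/- libraries lie between 67.9 and 79.5 CPM without V617F and between 51.2 and 59.5 CPM with it, below every Ezh2 +/- library.

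Jak2, which encodes the kinase that carries the V617F change, measured 210 ± 9.89 CPM in controls (n = 5) and 231 ± 10 CPM with V617F (n = 4). That difference did not pass (log2 0.13 ± 0.05, adjusted p = 0.0616). Jak2 was lower in Ezh2 -/- without V617F at 177 ± 9.65 CPM (-0.25 ± 0.05, adjusted p = 0.00086). V617F raised Jak2 in Ezh2 -/- (0.41 ± 0.05, adjusted p = 8.7e-06). These counts do not separate the mutant from the normal allele.

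Loss of both Ezh2 alleles without V617F (n = 4 against 5) raised genes that were almost silent in control MEPs. Lin28b, an RNA-binding protein of the fetal blood program, rose from 0.0917 ± 0.0574 to 14 ± 4.63 CPM (log2 7.23 ± 0.32, adjusted p = 1.3e-14). The 5 controls held 22 Lin28b counts together. Cdkn2a, the cell cycle inhibitor locus that Polycomb silences, rose from 0.0164 ± 0.0154 to 6.55 ± 2.03 CPM (adjusted p = 1.55e-07), with 4 counts over the 5 controls. Rps6ka6, a ribosomal S6 kinase family member, rose from 1.27 ± 0.45 to 64.6 ± 8.85 CPM (5.66 ± 0.32, adjusted p = 1.08e-12). The imprinted gene Peg10 rose by a log2 of 3.14 ± 0.22, Podxl, a sialomucin of blood progenitors and vessels, by 2.90 ± 0.20 (15.8 ± 2.98 to 118 ± 29.1 CPM), Cnnm1 by 3.79 ± 0.29 and Hs6st2 by 3.52 ± 0.25. Hdgfl3 (3.39 ± 0.45), Fam124a (3.24 ± 0.31), Ugt8a (3.13 ± 0.20), Pik3c2a (3.07 ± 0.34) and Khdrbs3 (2.87 ± 0.15) completed the 10 largest increases by the rule. Bmi1, a core subunit of the other Polycomb complex PRC1, rose from 88.6 ± 2.91 to 276 ± 16.8 CPM (1.65 ± 0.05, adjusted p = 1.82e-17).

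The largest decreases included lymphoid and antigen-presentation genes. Cd27 changed by -2.22 ± 0.48 (adjusted p = 0.00129), H2-Eb1 by -2.20 ± 0.54 (adjusted p = 0.00396), H2-Aa by -2.14 ± 0.54 (adjusted p = 0.00507) and Cd74 by -2.05 ± 0.52 (adjusted p = 0.00596; 108 ± 57.5 to 25.7 ± 7.86 CPM). The stem cell antigen Cd34 had the lowest fold change of the named genes (-3.95 ± 1.06, adjusted p = 0.00829), but without control replicate 5, which held 42.7 CPM, it was -2.17 (adjusted p = 0.111). The endothelial gene Tie1 (-1.98 ± 0.62, adjusted p = 0.0215) did not pass without control replicate 5 (adjusted p = 0.0868) or without Ezh2 -/- replicate 1 (0.0742), replicate 2 (0.0575) or replicate 3 (0.102).

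**Figure D2:**
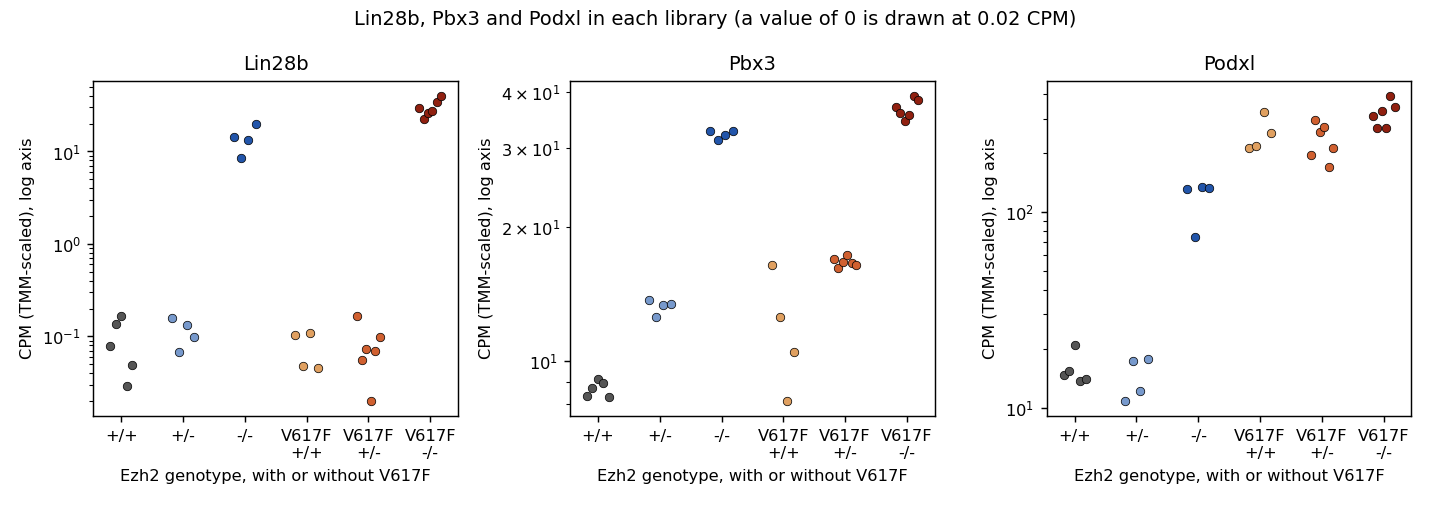
Levels of Lin28b, Pbx3 and Podxl in CPM (vertical axis, log scale) in each library (points) of the 6 genotype groups (horizontal axis); the library without a Lin28b count is drawn at 0.02 CPM. Lin28b lies between 8.51 and 39.5 CPM in the Ezh2 -/- libraries and at or under 0.166 CPM in the others, and Podxl is lowest in the groups without V617F that keep an Ezh2 allele.

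Some fetal-type genes and PRC1 subunits rose in this comparison, while most PRC2 subunits did not pass. Of 9 fetal-type genes tested, 4 rose, 1 fell and 4 did not pass (5 rose and 1 fell adjusted over the list alone), and Hmga2 rose by 4.36 ± 0.60 (adjusted p = 5.98e-06). Of 19 PRC1 subunits, 5 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone); Cbx2 rose by 0.78 ± 0.08 and Cbx6 by 0.60 ± 0.06. Of 12 PRC2 subunits, Epop (1.55 ± 0.16) and Phf19 (0.65 ± 0.11) rose and Ezh2 fell, and adjustment over the list alone called the same numbers; the list's median was 0.01 while its mean was -0.02. Among 11 developmental regulators, 4 rose and 1 fell (4 and 2 adjusted over the list alone): Cdkn2b rose by 3.54 ± 0.38 and Tbx3 changed by -2.90 ± 0.61. Of 15 Hox genes, 3 rose and 1 fell by either adjustment, with Hoxa4 up by 1.68 ± 0.20 and Hoxb2 at -1.59 ± 0.39. The p53 targets, which include growth-arrest and apoptosis genes, had 8 of 20 members higher and 1 lower (9 and 2 adjusted over the list alone), among them Phlda3 (2.21 ± 0.15), Zmat3 (1.15 ± 0.13) and Eda2r (1.02 ± 0.19). In the cell cycle list 19 of 38 members rose (28 adjusted over the list alone) with a median of 0.26; Pcna rose from 389 ± 23.9 to 497 ± 44.5 CPM.

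Some megakaryocyte, T and NK cell, monocyte and stem cell markers fell in Ezh2 -/- without V617F. The megakaryocyte and platelet list had 10 of 42 members lower and 32 that did not pass (13 lower adjusted over the list alone; median -0.92), including the platelet signalling regulator Rgs18 (-1.11 ± 0.30). Its mean log2 CPM was 1.92 to 2.43 in the Ezh2 -/- libraries, which overlaps control replicates 1, 2 and 4 (2.271, 1.991 and 2.391), and only control replicates 3 (3.43) and 5 (3.735) lay well above. Control replicate 5 was also the highest control in the T and NK cell, monocyte and stem lists (2.45, 3.43 and 3.871). The T and NK cell list had 8 of 22 lower by either adjustment (median -0.79), with Cd3e at -3.08 ± 0.48 and Cd5 at -2.44 ± 0.49. Of the monocyte, macrophage and dendritic list 5 of 27 fell by either adjustment (median -1.01). Of the stem and multipotent progenitor list 6 of 26 fell and 1 rose (7 and 1 adjusted over the list alone), with the transcription factor Sox4 at -1.17 ± 0.20 and Mllt3 at 0.44 ± 0.09. Of 37 interferon-stimulated genes 5 fell (Stat2 -0.60 ± 0.10), and of 22 immediate early and stress genes 5 fell (Ddit3 -0.60 ± 0.13, Ier2 -0.59 ± 0.16), both by either adjustment. Over all 13928 genes 1704 were lower, so the share in the interferon list is close to that of all genes. Of 25 inflammatory mediators 6 fell and 1 rose (8 and 1 adjusted over the list alone).

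The red-cell lists showed no common direction in this comparison. Of 36 erythroid genes 4 rose, 3 fell and 29 did not pass, by either adjustment, with a median of 0.18 and a mean of -0.01; the membrane skeleton gene Sptb rose by 0.84 ± 0.18. Of 15 heme biosynthesis genes 1 rose and 1 fell (1 fell adjusted over the list alone; median 0.17). Of 23 JAK-STAT5 targets 5 rose and 2 fell by either adjustment, with a median of -0.09 and a mean of 0.20; Socs2 rose by 1.68 ± 0.29 and Pim1 changed by -0.93 ± 0.19. The mast cell, basophil and eosinophil list had 2 of 17 lower (median -0.53), the stromal and endothelial list 1 of 8 lower (median -0.73) and the B cell list 1 of 16 lower (median 0.94, mean 0.40), each by either adjustment. No granulocyte gene passed (0 of 24 with edgeR; 2 at an unadjusted p under 0.05, 0 with DESeq2; median -0.88), and no ribosomal protein gene did (0 of 50; 0 at an unadjusted p under 0.05, 0 with DESeq2; median 0.01).

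For Ezh2 -/- without V617F, edgeR called 3307 of 13928 genes (23.7%), 1603 higher and 1704 lower; 603 of the higher and 430 of the lower changed at least 2-fold. Without Ezh2 -/- replicate 3 the count was 2096, with 1281 higher and 815 lower, and without control replicate 5 there were 1357 higher and 1075 lower. Among female libraries only the count was 1681. Camera with the preset correlation called 11 of 22 lists. The adjusted p was 2.44e-07 for cell cycle (0.751 with an estimated correlation), 0.000271 for fetal-type genes (0.122), 0.000656 for T and NK cell (0.751), 0.00096 for megakaryocyte and platelet (0.751) and 0.00872 for p53 targets (0.166). None of the 22 lists was called with an estimated correlation in any comparison. The granulocyte call (adjusted p = 0.0497) ended without control replicate 1 (0.0547), 2 (0.0531) or 5 (0.102) and without Ezh2 -/- replicate 2 (0.0524) or 3 (0.226). The interferon call (0.0294) ended without control replicate 2 (0.0531) or 5 (0.252) and without Ezh2 -/- replicate 2 (0.0524). Without control replicate 5 the developmental regulators were called as well (0.0413), and the inflammatory list was called without control replicate 2 (0.0295) or 4 (0.0244) or Ezh2 -/- replicate 4 (0.00389). The granulocyte call also ended without the sex term, and the interferon call among female libraries only. The granulocyte, interferon and stem calls ended without control replicate 5 and Ezh2 +/- replicates 2 and 5 together.

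Loss of 1 Ezh2 allele changed few genes. Without V617F (n = 4 against 5), edgeR called 2 of 13928 genes, with 384 at an unadjusted p under 0.05, and DESeq2 called 4. One was Ezh2 and the other was Pbx3, a homeobox cofactor of HOX proteins, which rose from 8.68 ± 0.359 to 13.3 ± 0.492 CPM (0.63 ± 0.10, adjusted p = 0.0182). Pbx3 was 32.2 ± 0.739 CPM in Ezh2 -/- (n = 4), 11.9 ± 3.49 CPM with V617F in Ezh2 +/+ (n = 4), 16.7 ± 0.4 CPM in Ezh2 +/- (n = 6) and 36.8 ± 1.82 CPM in Ezh2 -/- (n = 6). Its call in Ezh2 +/- ended when control replicate 1, 2, 3, 4 or 5 (adjusted p = 0.0761, 0.0501, 0.0559, 0.0642 and 0.0942) or Ezh2 +/- replicate 1, 4 or 5 (0.161, 0.146 and 0.0731) was left out. With V617F (n = 6 against 4), edgeR called 1 gene, Ezh2, with 881 at an unadjusted p under 0.05, and DESeq2 called 39. Leaving out V617F replicate 1, 3 or 4 gave 2, 37 and 4 calls and leaving out V617F Ezh2 +/- replicate 2 gave 6. In simulated data of this size, 62 of 100 genes changed by a log2 of 1 were recovered without V617F and 81 of 100 with it.

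In Ezh2 +/-, edgeR called 0 members of the tested lists apart from Ezh2 itself, and DESeq2 called 1 further member in each background. Adjusted over the list alone, 1 PRC1 subunit was lower without V617F. With V617F, 1 PRC1 subunit was higher and 1 developmental regulator lower by that adjustment. The megakaryocyte and platelet list is an example, with 0 of 42 called by edgeR in either background (0 and 3 at an unadjusted p under 0.05, 0 with DESeq2 in both). Camera with the preset correlation called the ribosomal protein list without V617F (median 0.10, adjusted p = 5.81e-30, 0.353 with an estimated correlation) and the cell cycle list (median 0.11, adjusted p = 5.24e-07, 0.994 with an estimated correlation), with 0 members called by edgeR (17 and 2 at an unadjusted p under 0.05, 0 with DESeq2). With V617F it called the ribosomal list at a median of -0.04 (adjusted p = 0.00456, 0.99 with an estimated correlation) and the T and NK cell list at -0.51 (adjusted p = 0.031, 0.99 with an estimated correlation). That ribosomal call ended without V617F replicate 3 (0.0562) or 4 (0.627) or V617F Ezh2 +/- replicate 4 (0.171). The T and NK call ended without V617F replicate 1 (0.302), 2 (0.129) or 3 (0.0657) or V617F Ezh2 +/- replicate 2 (0.135), 3 (0.173) or 4 (0.116), and both ended among female libraries only. Across genes, the fold changes of Ezh2 +/- and Ezh2 -/- had a Pearson r of 0.186 without V617F and 0.227 with it. These effects share their reference libraries, and genes are not independent replicates. The 10 simulated pairs of unchanged groups gave a mean r of 0.43 (0.401 to 0.463) and 0.643 (0.624 to 0.665). The real Ezh2 -/- effect widens the fold changes and can lower r, so these r values cannot be compared. The covariance was 0.0342 without V617F and 0.042 with it, against simulated means of 0.0403 and 0.0603. With the reference libraries split so that the effects shared none, r was 0.115 and -0.219 without V617F. With V617F it was -0.222 and 0.232.

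V617F in Ezh2 +/+ MEPs (n = 4 against 5) raised most granulocyte genes and 23 of 42 megakaryocyte and platelet genes. Podxl rose from 15.8 ± 2.98 to 251 ± 50.8 CPM (3.99 ± 0.21, adjusted p = 1.57e-12). The calcium-binding granulocyte protein gene S100a8 rose from 9.3 ± 4.07 to 113 ± 34.6 CPM (3.49 ± 0.52, adjusted p = 6.42e-05), and its partner S100a9 by 3.41 ± 0.51. The granule genes Camp (3.32 ± 0.53), Ltf (3.32 ± 0.49), Lcn2 (3.20 ± 0.52) and Ngp (3.01 ± 0.50) rose too, as did Fam124a (3.66 ± 0.31) and B3gnt7 (3.05 ± 0.38). Elane, the neutrophil elastase gene, rose by 3.11 ± 0.73 (adjusted p = 0.00327), a call not made among female libraries only (2.75, adjusted p = 0.0594). Camp, Ngp and Elane changed sign without a call when scores of the granulocyte, T and NK cell and stem lists were covariates (-0.47, -0.31 and -0.64). All of these genes are members of the granulocyte list, so their own levels enter that covariate.

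Several genes of lymphocytes and phagocytes were among those lowered by V617F. The interleukin receptor gene Il2rb fell from 28.6 ± 14.1 to 3.27 ± 1.85 CPM (-3.22 ± 0.53, adjusted p = 0.000186), the chemokine gene Ccl5 changed by -3.04 ± 0.59, and the T cell factor Tcf7 by -2.91 ± 0.51. Cd7 (-2.66 ± 0.44), Id2 (-2.37 ± 0.46), Ablim1 (-2.22 ± 0.59), H2-Aa (-2.21 ± 0.54) and Cd74 (-2.55 ± 0.54) fell as well. The macrophage receptor gene Csf1r (-2.61 ± 0.68) and the heme oxygenase gene Hmox1 (-2.41 ± 0.63) fell in all libraries together and did not pass among female ones (adjusted p = 0.0579 and 0.0729). Il2rb, Ccl5, Tcf7, Cd7 and Ablim1 changed sign without a call under the lineage score covariates (0.67, 1.28, 0.18, 0.25 and 1.43). Ccl5 and Tcf7 are themselves members of the T and NK cell list used as a covariate.

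By list, 17 of 24 granulocyte genes rose with V617F in Ezh2 +/+ and 7 did not pass (18 rose adjusted over the list alone; median 2.72). In the megakaryocyte and platelet list 23 of 42 rose, 1 fell and 18 did not pass (31 and 1 adjusted over the list alone; median 1.28), with platelet factor Pf4 rising from 23 ± 19.6 to 101.5 ± 61 CPM (2.05 ± 0.48), Mmrn1 by 2.48 ± 0.55 and Cd63 by 1.59 ± 0.34. In the T and NK cell list 16 of 22 fell (18 adjusted over the list alone; median -2.35), including Bcl11b (-3.08 ± 0.49). In the monocyte, macrophage and dendritic list 15 of 27 fell and 2 rose (18 and 3 adjusted over the list alone), with Itgax at -3.10 ± 0.54 and Lyz2 at 1.86 ± 0.38, and in the B cell list 5 of 16 fell (9 adjusted over the list alone; Cd22 -3.24 ± 0.62). Of 37 interferon-stimulated genes 14 fell (18 adjusted over the list alone), with Stat2 at -0.75 ± 0.10 and Irf9 at -0.68 ± 0.13. Of 23 JAK-STAT5 targets 8 rose and 3 fell by either adjustment, with a median of -0.11 and a mean of 0.43: the erythroid hormone gene Erfe rose by 2.47 ± 0.25, Osm by 1.08 ± 0.13 and Ccnd2 by 0.66 ± 0.08. Of 15 Hox genes 5 rose by either adjustment (Hoxa10 1.48 ± 0.32), and in the stem list 6 of 26 rose and 4 fell (8 and 6 adjusted over the list alone), with Mecom at 2.54 ± 0.54 and Satb1 at -1.95 ± 0.46.

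The sex check genes matched the labels except in V617F replicate 1, labelled female, where Xist, the RNA that silences an X chromosome, measured 1.03 CPM. Here edgeR called 3288 genes (23.6%), 1355 higher and 1933 lower, of which 578 and 568 changed at least 2-fold. The excess of lower genes shrank with DESeq2 size factors (1646 higher, 1826 lower) and with DESeq2 (1883 and 2006). Among female libraries only the count was 1875. With the lineage scores as covariates it was 2298, of which 1334 were higher and 964 lower, and 920 of these were among the 3288. Camera called 9 of 22 lists, with adjusted p = 2.18e-11 for granulocyte and for T and NK cell, 9.73e-09 for megakaryocyte and platelet and 1.57e-05 for interferon (each 0.736 with an estimated correlation). The JAK-STAT5 call (adjusted p = 0.0499) ended without control replicate 2 (0.076), 3 (0.0888) or 4 (0.138) or V617F replicate 1 (0.134) or 3 (0.0582). The call of the ribosomal list (median 0.05, adjusted p = 0.0382) ended without control replicate 1 (0.207) or 3 (0.0888) or V617F replicate 3 (0.0739) or 4 (0.19). Both calls ended among female libraries only. The cell cycle list was called without control replicate 4 (0.015) or V617F replicate 1 (0.00386), and the fetal-type list without control replicate 5 (0.0463).

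**Figure D3:**
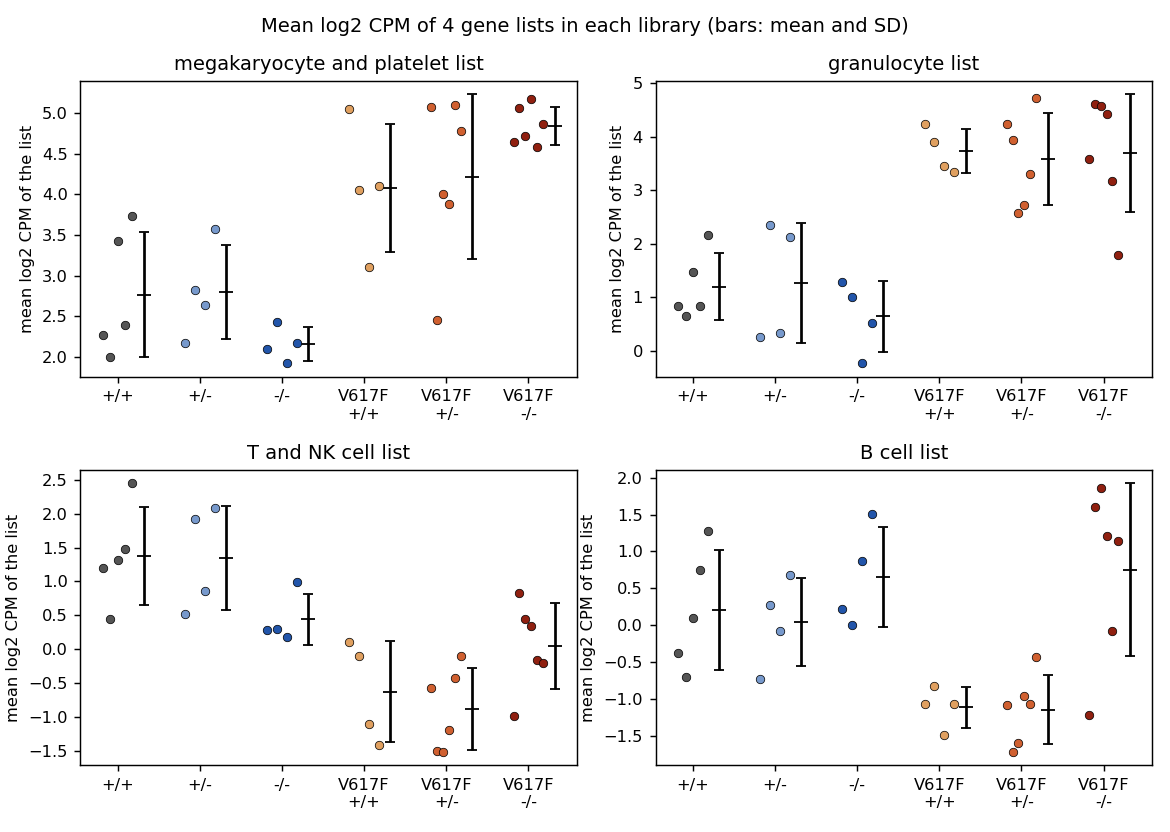
Mean log2 CPM of the members of 4 lists (vertical axis) in each library (points) of the 6 genotype groups (horizontal axis), with group mean and SD as a bar. The megakaryocyte score averages 2.76 in controls, 2.15 in Ezh2 -/- and 4.84 in V617F Ezh2 -/-. The B cell score averages -1.11 in V617F Ezh2 +/+ and 0.75 in V617F Ezh2 -/-, where replicate 1 lies at -1.219.

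Loss of both Ezh2 alleles on the V617F background (n = 6 against 4) again raised Lin28b and Bmi1. Lin28b rose from 0.0766 ± 0.0343 to 30 ± 6 CPM (8.77 ± 0.37, adjusted p = 3.6e-15), with 13 counts over the 4 libraries of the lower group, and Bmi1 from 93.9 ± 2.33 to 270 ± 20.5 CPM (1.54 ± 0.05, adjusted p = 8.02e-17). The actin regulator gene Evl rose from 1.6 ± 1.05 to 19.4 ± 1.87 CPM (3.48 ± 0.42, adjusted p = 1.42e-06) and the chromatin remodeller gene Chd7 by 2.43 ± 0.20. Rps6ka6 (3.35 ± 0.30), Cnnm1 (2.70 ± 0.29), Peg10 (2.41 ± 0.22) and Pik3c2a (2.38 ± 0.34), also named without V617F, rose here too. The matrix genes Nid1 (2.82 ± 0.20), Ltbp4 (2.78 ± 0.32) and Thbs1 (2.46 ± 0.46) rose, and so did the kinesin gene Kif21a (2.54 ± 0.26). Among the genes named by the size rule, which asks for a minimum level and no overlap, the largest decrease after Ezh2 was Susd2, from 13.6 ± 5.21 to 5.11 ± 1.16 CPM (-1.31 ± 0.22, adjusted p = 0.000137), followed by Slc26a1 (-1.20 ± 0.25), the protease gene Hpn (-1.08 ± 0.18) and the glutathione transferase gene Gsta4 (-1.06 ± 0.24). Prelid2 (-0.93 ± 0.17), Trpv2 (-0.92 ± 0.12), Fads3 (-0.90 ± 0.16), Pnp2 (-0.90 ± 0.21) and Dcaf12l1 (-0.86 ± 0.17) fell by less than 2-fold.

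Among V617F libraries, 10 of 16 B cell genes were higher in Ezh2 -/- by either adjustment (median 3.07). The rise was not shared by all libraries. The list's mean log2 CPM was -1.219 in V617F Ezh2 -/- replicate 1, within the V617F Ezh2 +/+ libraries (-1.488 to -0.825). It was -0.076 in replicate 5 and 1.137 to 1.862 in the other replicates. Cd79a, a subunit of the B cell receptor, rose from 0.328 ± 0.117 to 3.66 ± 2.31 CPM (3.44 ± 0.60, adjusted p = 0.000168), Blnk by 3.0 ± 0.62 and Pou2af1 by 3.28 ± 0.70. The lymphoid progenitor gene Dntt rose from 0.747 ± 0.32 to 11.1 ± 7.38 CPM (3.74 ± 0.95, adjusted p = 0.00563). Of 22 T and NK cell genes 3 rose, 1 fell (Cd3e, -2.20 ± 0.49) and 18 did not pass, by either adjustment (median 0.41). Of 37 interferon-stimulated genes 17 rose (27 adjusted over the list alone; median 0.63), including Ifi27l2a (3.07 ± 0.56), Mx2 (1.54 ± 0.32) and Usp18 (1.49 ± 0.28). Of 9 fetal-type genes 6 rose by either adjustment (Plagl1 3.20 ± 0.56) and of 11 developmental regulators 5 (Cdkn2b 1.97 ± 0.37, Wnt10b 1.89 ± 0.47). Of 15 Hox genes 4 rose and 1 fell (Hoxa4 1.53 ± 0.20, Hoxb2 -1.45 ± 0.34) and of 20 p53 targets 7 rose and 1 fell (Phlda3 1.56 ± 0.15, Sesn2 -0.74 ± 0.12), all by either adjustment. Of 12 PRC2 subunits 4 rose and 5 fell, with Epop at 1.74 ± 0.17 and Eed at -0.37 ± 0.08, and of 19 PRC1 subunits 9 rose and 3 fell (9 and 4 adjusted over the list alone). Of 23 JAK-STAT5 targets 8 rose (10 adjusted over the list alone; Socs2 1.25 ± 0.28, Myc 0.49 ± 0.11). The erythroid carbonic anhydrase gene Car1 changed by -0.74 ± 0.16, in a list where 2 of 36 fell, 1 rose and 33 did not pass.

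With V617F, edgeR called 3709 genes (26.6%) between Ezh2 -/- and Ezh2 +/+, 1814 higher and 1895 lower, and at least 2-fold changes were 802 higher against 44 lower. Leaving out V617F replicate 2 gave 2368 calls (1315 higher, 1053 lower) and leaving out V617F replicate 4 gave 1954 (1191 higher, 763 lower). Without V617F Ezh2 -/- replicate 2 or 4 the lower genes numbered 1039 and 1098, and female libraries only gave 2268 calls (1366 higher, 902 lower). Camera called 10 of 22 lists, among them interferon (adjusted p = 1.15e-06, 0.619 with an estimated correlation), fetal-type (4.14e-05, 0.107), ribosomal (median -0.10, 0.000167, 0.713) and B cell (0.000944, 0.619). The PRC1 call (0.0274) ended without V617F replicate 1 (0.0591) and the Hox call (0.0203) without V617F replicate 4 (0.11). The Hox and megakaryocyte calls ended among female libraries only. Without V617F replicate 1 the stem (0.0101), heme (0.0323) and cell cycle (0.00821) lists were called too. The stem list was also called without V617F Ezh2 -/- replicate 1 (0.0429), 5 (0.0405) or 6 (0.0361), cell cycle without replicate 5 (0.0445) or 6 (0.032), T and NK cell without replicate 1 (0.0327) and the mast cell list without replicate 6 (0.0213) of the same group.

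**Figure D4:**
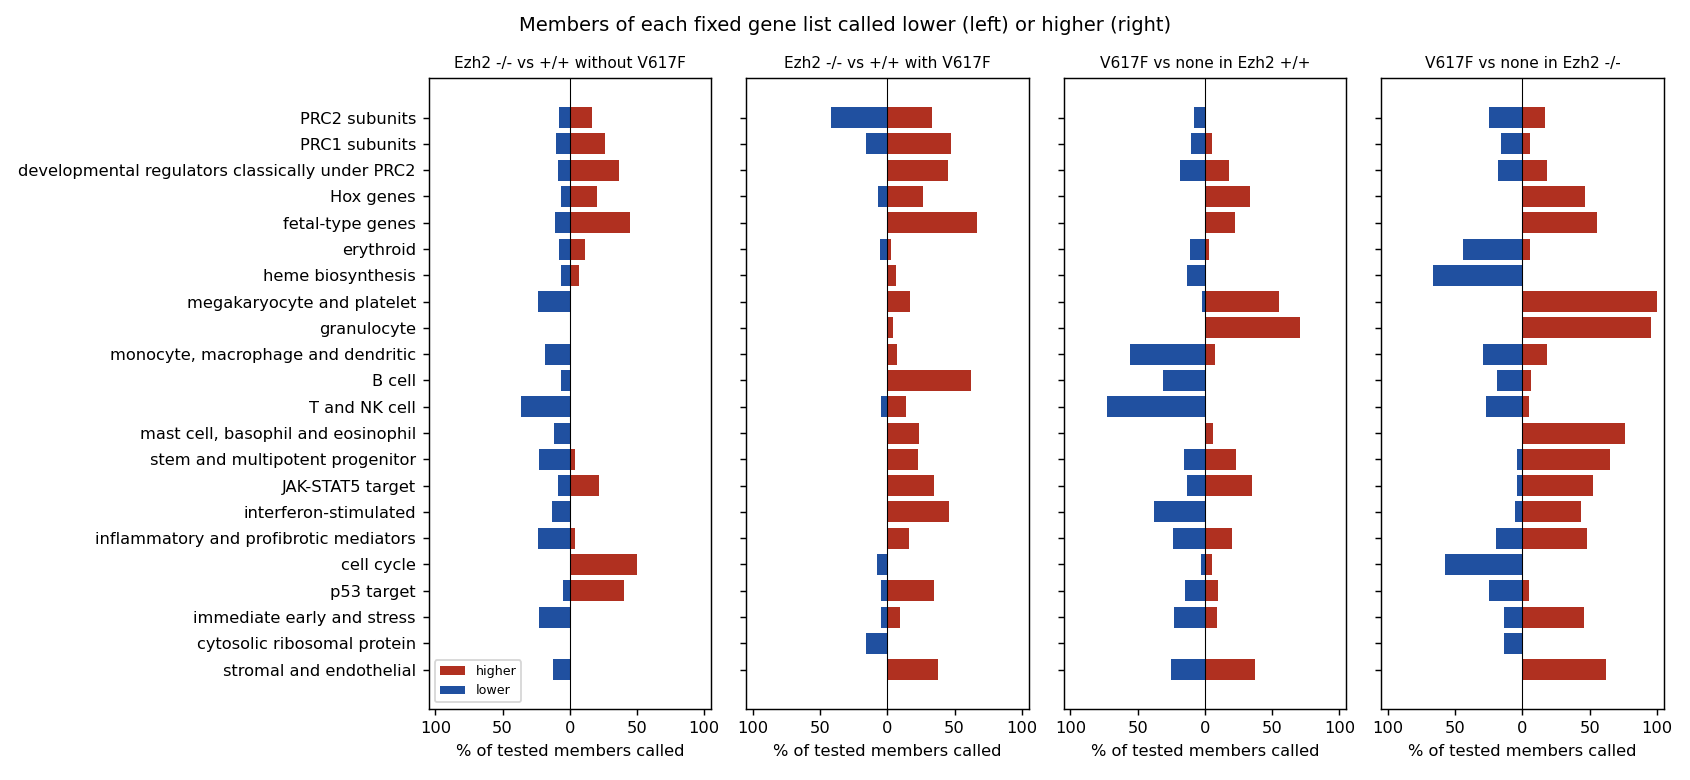
Percent of tested members (horizontal axis) of each of 22 lists (vertical axis) called lower (bars to the left) or higher (bars to the right) in 4 comparisons (panels). All 42 megakaryocyte and platelet genes are higher with V617F in Ezh2 -/-, against 23 of 42 in Ezh2 +/+, and 10 of 16 B cell genes are higher in V617F Ezh2 -/-.

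V617F in Ezh2 -/- MEPs (n = 6 against 4) raised every tested megakaryocyte and platelet gene, 42 of 42 (median 2.62, and 42 adjusted over the list alone). Pf4 rose from 7.43 ± 1.6 to 161 ± 38.8 CPM (4.04 ± 0.57, adjusted p = 4.93e-05), the adhesion receptor gene Selp from 1.34 ± 0.612 to 33.2 ± 5.65 CPM (4.11 ± 0.69), and Tbxas1 (4.07 ± 0.60), Trpc6 (3.96 ± 0.64), Esam (3.89 ± 0.65) and Alox12 (3.89 ± 0.56) rose too. Cd34 rose by 4.39 ± 1.07 (adjusted p = 0.00344), the metalloproteinase inhibitor gene Timp3 by 3.94 ± 0.58, Clu by 4.16 ± 0.64, Scarf1 by 3.99 ± 0.70 and Elane by 3.85 ± 0.83. The STAT5 target Cish rose from 6.45 ± 1.37 to 31 ± 5.76 CPM (2.22 ± 0.23, adjusted p = 1e-06), Osm by 1.16 ± 0.13, Ccnd2 by 0.81 ± 0.08 and Podxl by 1.42 ± 0.19. The signalling inhibitor gene Spry4 fell from 10.4 ± 1.45 to 3.09 ± 0.335 CPM (-1.67 ± 0.17, adjusted p = 1e-06) and the epoxide hydrolase gene Ephx2 from 50.4 ± 3.9 to 16.9 ± 2.78 CPM (-1.58 ± 0.17). Ccl5 (-2.13 ± 0.54), Hmox1 (-2.03 ± 0.57), Il2rb (-1.89 ± 0.48), Ehd2 (-1.40 ± 0.17), Gsta4 (-1.39 ± 0.24), Hpn (-1.37 ± 0.18), Slc26a1 (-1.32 ± 0.24) and Trim2 (-1.29 ± 0.21) fell as well. Elane, Il2rb, Slc26a1 and Trim2 changed sign without a call under the lineage score covariates (-1.08, 0.12, 0.20 and 0.54). Elane is itself a member of the granulocyte list used as a covariate.

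Of 24 granulocyte genes 23 rose with V617F in Ezh2 -/- by either adjustment (median 3.38; S100a8 3.73 ± 0.57, Mmp9 3.03 ± 0.44). Of 17 mast cell, basophil and eosinophil genes 13 rose (13 and 1 lower adjusted over the list alone; Alox5 1.76 ± 0.27), and of 26 stem and multipotent progenitor genes 17 rose and 1 fell by either adjustment (Meis1 2.49 ± 0.43, Mycn 3.39 ± 0.55). Of 36 erythroid genes 16 fell, 2 rose and 18 did not pass, by either adjustment, with the water channel gene Aqp1 at -0.49 ± 0.10 and the progenitor factor Gata2 rising by 1.21 ± 0.25. Of 15 heme genes 10 fell (11 adjusted over the list alone; Alad -0.50 ± 0.10), and of 38 cell cycle genes 22 fell and 16 did not pass (25 fell adjusted over the list alone; Mcm5 -0.37 ± 0.08). Under the lineage score covariates Aqp1, Gata2, Alad and Mcm5 changed sign without a call (0.01, -0.20, 0.01 and 0.11). Of 22 immediate early and stress genes 10 rose and 3 fell (12 and 4 adjusted over the list alone; Egr1 2.52 ± 0.33), of 37 interferon-stimulated genes 16 rose and 2 fell, and of 15 Hox genes 7 rose (8 adjusted over the list alone). Of 23 JAK-STAT5 targets 12 rose and 1 fell (13 and 1 adjusted over the list alone), and of 25 inflammatory mediators 12 rose and 5 fell by either adjustment, with Vegfa at 0.64 ± 0.09.

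For V617F in Ezh2 -/-, edgeR called 5795 genes (41.6%), 2665 higher and 3130 lower, with 1347 and 239 at least 2-fold. The balance turned with DESeq2 size factors (2878 higher and 2604 lower) and with DESeq2 (3138 and 2814), and 549 genes were called with the lineage scores as covariates. Without Ezh2 -/- replicate 3 the count was 3197. Camera called 14 of 22 lists, including megakaryocyte and platelet (adjusted p = 3.12e-23, 0.404 with an estimated correlation), granulocyte (9.08e-13, 0.404), cell cycle (1.03e-06, 0.465) and stem (1.31e-06, 0.433). For heme biosynthesis it was 0.000728 (0.433 with an estimated correlation) and for erythroid genes 0.00906 (0.528). The fetal-type call (0.0379) ended without V617F Ezh2 -/- replicate 5 (0.0557) or 6 (0.0513). The ribosomal list was called without Ezh2 -/- replicate 1 (0.00878) or 2 (0.00959) or V617F Ezh2 -/- replicate 1 (0.00541), and the T and NK cell list without Ezh2 -/- replicate 3 (0.0273) or V617F Ezh2 -/- replicate 2 (0.0192).

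V617F in Ezh2 +/- (n = 6 against 4) raised Podxl from 14.5 ± 3.54 to 233 ± 48.2 CPM (4.0 ± 0.23, adjusted p = 1.29e-11), Erfe by 2.15 ± 0.26, Cish by 1.53 ± 0.23, Osm by 0.88 ± 0.13 and Ccnd2 by 0.69 ± 0.08. Ltf (3.09 ± 0.53, adjusted p = 0.000412), Il2rb (-3.42 ± 0.48, adjusted p = 5.73e-05) and Tcf7 (-3.04 ± 0.46, adjusted p = 0.000106) were called with all libraries. Without control replicate 5 and Ezh2 +/- replicates 2 and 5 they were not (3.44, -2.28 and -1.96, adjusted p = 0.0553, 0.15 and 0.21). That fit leaves only male Ezh2 +/- libraries against female V617F ones. Sex is separated from V617F there only by the sex term, which is estimated from the other groups. Under the lineage score covariates Il2rb and Tcf7 changed sign without a call (1.05 and 0.49). Tcf7 is itself a member of the T and NK cell list used as a covariate. Of 22 T and NK cell genes 17 fell (20 adjusted over the list alone; median -3.04) and of 24 granulocyte genes 14 rose (15; median 2.17). Of 42 megakaryocyte genes 14 rose (33 adjusted over the list alone; median 1.33) and of 27 monocyte, macrophage and dendritic genes 16 fell and 1 rose (19 and 3 adjusted over the list alone). Of 36 erythroid genes 8 fell (10 fell and 1 rose adjusted over the list alone; median -0.24). Here edgeR called 1374 genes (9.9%), 467 higher and 907 lower, with DESeq2 at 830 higher and 959 lower, a share of higher genes of 46.4% against 34%. Without Ezh2 +/- replicate 2 the count was 802, without replicate 5 it was 706 and without V617F Ezh2 +/- replicate 2 it was 1893. Without control replicate 5 and Ezh2 +/- replicates 2 and 5 together it was 94, with 65 higher and 29 lower. The count was 313 in a fit of the compared groups only, 2170 without the sex term and 112 with the lineage scores. Of 40 splits of these libraries, 4 called as many genes, so chance is not excluded. Camera called 12 of 22 lists, led by T and NK cell (adjusted p = 1.48e-20, 0.175 with an estimated correlation). The interferon call (0.000127) ended without Ezh2 +/- replicate 5 (0.35). The fetal-type call (0.0277) ended without Ezh2 +/- replicate 1 (0.0692) or 4 (0.139) and without V617F Ezh2 +/- replicate 3 (0.0539) or 6 (0.0787). Among female libraries only, the fetal-type and JAK-STAT5 calls ended. The monocyte and interferon calls ended without control replicate 5 and Ezh2 +/- replicates 2 and 5 together.

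The effect of V617F differed between Ezh2 -/- and Ezh2 +/+ in the interaction test. Podxl had a lower V617F effect in Ezh2 -/- (interaction -2.57 ± 0.27, adjusted p = 7.07e-06); without V617F it stood at 118 ± 29.1 CPM there, against 15.8 ± 2.98 CPM in controls. Fam124a (-3.10 ± 0.40, adjusted p = 0.000188), Rps6ka6 (-2.31 ± 0.40), the secreted WNT inhibitor gene Sfrp4 (-1.93 ± 0.31) and Cpd (-1.79 ± 0.25) had negative interactions too. Positive interactions were found for the interferon-induced genes Mx2 (2.47 ± 0.44, adjusted p = 0.00479), Ifi27l2a (3.76 ± 0.75, adjusted p = 0.00901) and Mx1 (2.46 ± 0.54, adjusted p = 0.0125), the T cell factor Bcl11b (3.75 ± 0.64, adjusted p = 0.00347), Sox4 (1.25 ± 0.28) and Cd48 (1.11 ± 0.23). Mx2 went from 2.39 ± 1.06 to 0.981 ± 0.219 CPM with V617F in Ezh2 +/+ and from 1.26 ± 0.0864 to 2.88 ± 0.913 CPM in Ezh2 -/-. Of 37 interferon-stimulated genes 21 had a positive interaction (29 adjusted over the list alone; median 1.08), of 42 megakaryocyte and platelet genes 11 (12; median 1.2), and of 38 cell cycle genes 16 had a negative one (24 adjusted over the list alone; median -0.34).

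The largest positive interactions by the rule were Cd74 (2.83 ± 0.73, adjusted p = 0.0195), H2-Aa (2.72 ± 0.74, adjusted p = 0.0219), H2-Eb1 (2.68 ± 0.73, adjusted p = 0.0222), Oas2 (2.61 ± 0.67, adjusted p = 0.0195) and Slc35d3 (2.54 ± 0.60, adjusted p = 0.015). Cd74 changed by -2.55 ± 0.54 with V617F in Ezh2 +/+ and stood at 25.7 ± 7.86 CPM without and 29.4 ± 17.9 CPM with V617F in Ezh2 -/-. All 5 calls ended without Ezh2 -/- replicate 3 (adjusted p = 0.0572, 0.0623, 0.0624, 0.0572 and 0.053), the first 3 also without control replicate 1 (0.0508, 0.0547 and 0.0559), and those of H2-Aa and H2-Eb1 without V617F replicate 4 (0.0525 and 0.0531). Jak2 had a positive interaction (0.28 ± 0.07, adjusted p = 0.0189), not called without Ezh2 -/- replicate 3 (0.0655).

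For the interaction of V617F with Ezh2 -/-, edgeR called 2663 genes (19.1%), 1180 positive and 1483 negative, of which 526 and 90 reached 2-fold. Female libraries only gave 128 calls, 87 positive and 41 negative, the fit without control replicate 5 and Ezh2 +/- replicates 2 and 5 gave 1199, and the lineage scores as covariates gave 949. Leaving out Ezh2 -/- replicate 3 gave 297 calls and replicate 1 gave 1716. Control replicate 1 gave 533 and replicate 5 gave 1068. V617F replicates 1, 2, 3 and 4 gave 4633, 1665, 1451 and 951, and V617F Ezh2 -/- replicates 2 and 4 gave 1391 and 1763. Camera called 13 of 22 lists, including interferon (adjusted p = 1.2e-09), cell cycle (4.54e-09), megakaryocyte and platelet (8.52e-08) and T and NK cell (1.4e-05), each at 0.636 with an estimated correlation. The monocyte call (0.0178) ended without control replicate 5 (0.0614) and the heme call (0.0207) without V617F replicate 3 (0.0853) or among female libraries only. For the interaction with Ezh2 +/-, edgeR called 0 genes, with 937 at an unadjusted p under 0.05, and DESeq2 called 13; Ezh2 itself was at -0.06 ± 0.12 (adjusted p = 0.962). Camera with the preset correlation called 4 lists there, with 0 members called by edgeR or DESeq2. They were ribosomal (median -0.14, adjusted p = 2.06e-19, 0.766 with an estimated correlation; 22 members at an unadjusted p under 0.05), cell cycle (-0.11, 0.00182, 0.983; 3 members), heme (-0.18, 0.0154, 0.983; 0 members) and PRC1 (0.03, 0.0311, 0.143; 4 members). The cell cycle call ended without Ezh2 +/- replicate 2 (0.053) or V617F Ezh2 +/- replicate 1 (0.132). The heme call ended without Ezh2 +/- replicate 2 (0.06), V617F replicate 3 (0.164) or V617F Ezh2 +/- replicate 1 (0.084) or 5 (0.119), and both ended among female libraries only. The PRC1 call ended without Ezh2 +/- replicate 5 (0.0518), V617F replicate 2 (0.0516) or V617F Ezh2 +/- replicate 1 (0.0557).

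The Ezh2 -/- effects without and with V617F, which share no libraries, had a Pearson r of 0.437 and a Spearman rho of 0.096 across 13928 genes, which are not independent replicates. Both comparisons called 818 genes higher, Lin28b and Bmi1 among them, where independent calls of these numbers would share 208.8. Both called 257 lower, against 231.8, and 62 genes were called in opposite directions, against 440. For V617F in Ezh2 +/+ and Ezh2 -/- the r was 0.569 and the rho 0.338. There 595 genes were higher in both, such as Pf4, S100a8 and Ccnd2 (259.3 if independent), 751 lower in both, such as Il2rb and Ccl5 (434.4), and 101 opposite (674.4).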

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

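The tests of a mislabelled male sample and of 1 X chromosome were chosen after the Xist value was seen. The test of 2 active X chromosomes was recorded as earlier. It names the library with little Xist, so it is not treated as chosen in advance either. V617F Ezh2 +/+ replicate 1 is labelled female, and its Xist stood at 1.03 CPM against 1520 to 2630 CPM in the other 22 female libraries and at most 1.09 CPM in the 6 male ones. A mislabelled male whose cells keep the Y chromosome is excluded by the Y-linked gene Ddx3y, at 0 CPM against 116 to 164 CPM in males. Ddx3y cannot assign a sex to cells without a Y chromosome. The X-linked minus autosomal median of 0.02 (317 and 9522 genes) excludes 2 active X chromosomes. The mean of 4 genes that escape X inactivation was 7.34 log2 CPM, against 7.41 to 7.52 in males and 7.65 to 8 in the other females, which is in line with a single X chromosome in these cells; no biological explanation from the design was tested.

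The tests of a lower share of the main cell type, of granulocytes in the sort and of a varying share of stem-like or megakaryocyte-primed cells were chosen after the higher granulocyte and megakaryocyte lists with V617F were seen. A lower share of the main cell type would raise T and NK cell genes as well, if the mix of the other sorted cells stayed the same. The T and NK cell list's median was -2.35 in Ezh2 +/+. The B cell median was -1.78 and the granulocyte median 2.72 there, so an unchanged mix cannot be assumed and the test does not decide. Over the 16 V617F libraries, as deviations from 3 group means, megakaryocyte and granulocyte scores had a Pearson r of 0.23 (bootstrap -0.11 to 0.65, permutation p = 0.39, adjusted 0.39 in a family of 2) and a Spearman rho of 0.46 (permutation p = 0.0777); without the 2 farthest samples r was 0.46, so granulocytes carrying both lists cannot be told apart from separate sources. Megakaryocyte and stem scores had an r of 0.89 (0.81 to 0.95, permutation p = 5e-05, adjusted 0.0001) and a rho of 0.94 (permutation p = 9e-05), with r 0.88 without the 2 farthest, and the lists share 0 genes. This is consistent with libraries that vary in their share of stem-like or megakaryocyte-primed cells, and expression changes within cells were not separated from it.

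Leaving out each library in turn had been planned. The tests without Ezh2 -/- replicate 3 and without control replicate 5 and Ezh2 +/- replicates 2 and 5 concerned genes already called for the interaction. None of them is treated as chosen in advance. The interaction of V617F with Ezh2 -/- was flagged because effects differed between groups, with 2663 genes called. Without Ezh2 -/- replicate 3 the called genes kept a median 0.89 of their log2 interaction, and 297 were called. Without the 3 other libraries the ratio was 0.93 and 1199 were called. Of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, 3 stayed called without these 3 libraries (Cd74 at 2.54 ± 0.70, edgeR adjusted p = 0.0378). Of these libraries, only control replicate 5 belongs to the groups that this interaction compares. Left out singly, the libraries compared here gave median ratios of 0.89 to 1.11, the lowest without Ezh2 -/- replicate 3. The genes were picked with these libraries included, and 1 library moves a group mean only in part. The ratios therefore cannot decide whether the interaction rests on 1 library. Most calls, those of Cd74, H2-Aa and H2-Eb1 among them, ended without Ezh2 -/- replicate 3.

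The split tests were all chosen before the results were seen. There were 40 splits per comparison, the real one included. Only the real one reached its count for Ezh2 -/- without V617F (1 split with as many calls, 3307 against a highest other of 1200) and with V617F (1, 3709 against 19). The same held for V617F in Ezh2 +/+ (1, 3288 against 2151) and in Ezh2 -/- (1, 5795 against 4136). This makes chance unlikely in these comparisons and cannot exclude it. Other splits reached the real count for Ezh2 +/- with V617F (7 splits, 1 against 3358) and V617F in Ezh2 +/- (4, 1374 against 3002), so chance stays open there. The splits cannot decide for the interactions with Ezh2 -/- (1, 2663 against 413) and Ezh2 +/- (40, 0 against 394). They mixed V617F labels within each Ezh2 genotype, so the V617F effect itself became spread between libraries and can lower the counts. A count of 1 is the lowest these splits can give, and it was not adjusted over the 9 comparisons. For Ezh2 +/- without V617F only the real split had as many calls (1, 2 against 0). Of these 2 calls, 1 is the deleted gene Ezh2 itself, and the other, Pbx3, ended when most of the single libraries were left out. A split that calls several times the real count, such as the 3358 against 1, points to a structure of the samples, whose cause was not tested. Splits with 2151 and 4136 calls also occurred where only the real split reached its count. V617F Ezh2 +/- replicates 1, 5 and 6 lay at 33.4 to 53.5 on the first principal component and replicates 2, 3 and 4 at -31.3 to 0.1, with a chi-square per degree of freedom of 47.3 to 133.2 between these sets and 4.9 to 24.6 within them.

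The interaction test flagged Cd74 (2.83), H2-Aa (2.72), H2-Eb1 (2.68), Oas2 (2.61), Slc35d3 (2.54), Fam124a (-3.10), Podxl (-2.57), Rps6ka6 (-2.31), Sfrp4 (-1.93) and Cpd (-1.79). It flagged 13 list medians by camera with the preset correlation and none with an estimated one. They were B cell at 2.01, mast cell at 1.68, T and NK cell at 1.43, stromal at 1.37, stem at 1.22, megakaryocyte at 1.2, interferon at 1.08, immediate early at 0.88, monocyte at 0.77, inflammatory at 0.56, ribosomal at -0.09, heme at -0.30 and cell cycle at -0.34.

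Single libraries far from the rest of their group were flagged in 11 of 174 measures, and chance flags about 1 in 20 groups. In control replicate 5 the 10 highest genes held 6.34% of counts (4.61 to 4.93% in the other controls), genes without a name held 2.68% (0.88 to 1.21%) and the interferon score was 4.66 log2 CPM (3.69 to 3.9). Ezh2 +/- replicate 5 was high in p53 targets (4.26 against 4.1 to 4.12) and replicate 1 low in ribosomal genes (9.62 against 9.8 to 9.81). Ezh2 -/- replicate 4 was high in T and NK cell genes (1.0 against 0.18 to 0.3) and replicate 3 high in ribosomal genes (9.81 against 9.64 to 9.66). V617F replicate 1 was low in erythroid genes (6.94 against 7.13 to 7.16) and high in JAK-STAT5 targets (4.08 against 3.46 to 3.55). V617F Ezh2 +/- replicate 2 was low in PRC1 subunits (4.86 against 4.94 to 4.98), and V617F Ezh2 -/- replicate 1 low in JAK-STAT5 targets (4.0 against 4.23 to 4.34).

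Of 1800 pairs of a named gene and a group, 83 had a library that stood apart, spread over 21 libraries. Control replicates 1, 3, 4 and 5 held 1, 1, 4 and 14 such genes, Ezh2 +/- replicates 1, 4 and 5 held 3, 6 and 8, and Ezh2 -/- replicates 2, 3 and 4 held 3, 4 and 5. V617F replicates 1, 2 and 3 held 6, 2 and 1, V617F Ezh2 +/- replicates 1, 2 and 5 held 1, 4 and 3, and V617F Ezh2 -/- replicates 1, 3, 4, 5 and 6 held 7, 1, 1, 1 and 7.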

How the results depend on the processing

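Of 578 results on single genes, all that an alternative gave a value for kept their direction except under the lineage score covariates, where 80 changed sign, 267 kept direction without a call and 231 kept the call. The call was lost by 178 among female libraries only, 164 without the 3 libraries that stand apart, 88 with the compared groups only (14 had no value there), 40 with no filter, 18 without the sex term, 12 with DESeq2 size factors and 6 with DESeq2. Leaving out 1 library at a time, counted once per gene result and library left out, lost the call in 823 cases and kept it in 5443. Fewer libraries lower the power by construction, and otherwise the cause was not tested. In the data simulated at this depth, between 62 and 82 of 100 changes of a log2 of 1 were recovered, so smaller or rarer changes are missed.

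Female libraries only gave 1681 calls for Ezh2 -/- and 0 for Ezh2 +/- without V617F, 1875 for V617F in Ezh2 +/+, 2268 for Ezh2 -/- and 20 for Ezh2 +/- with V617F, and 128 for the interaction with Ezh2 -/-. DESeq2 gave 4 and 39 for Ezh2 +/- without and with V617F and 13 for the interaction with Ezh2 +/-. The compared groups only gave 1 and 2 for Ezh2 +/- and 313 for V617F in Ezh2 +/-. Without the sex term V617F in Ezh2 +/- had 2170. Without the 3 libraries that stand apart Ezh2 +/- without V617F had 1, V617F in Ezh2 +/- 94 and the interaction with Ezh2 -/- 1199. With lineage scores Ezh2 +/- with V617F had 14, V617F in Ezh2 -/- 549, V617F in Ezh2 +/- 112 and the interactions 949 and 36.

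With the replicate number as a block, Ezh2 +/- without V617F had 1 call and the interaction with Ezh2 -/- 1623. The numbers are not stated to pair the samples. Over 2000 genes, 62 pairs with the same number had a mean r of 0.032 (-0.39 to 0.393; 22 over 0.1), 286 other pairs -0.007, and 7 of 29 libraries correlated best with their own number. Among single genes the block lost 45 calls, and in Ezh2 -/- without V617F it ended the granulocyte and interferon list calls, for V617F in Ezh2 -/- the fetal-type call and for the interaction with Ezh2 -/- the monocyte call.

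For the lists, an estimated correlation gave 0 calls in all 9 comparisons. The fry test gave 7 for Ezh2 -/- without V617F, 0 and 1 for Ezh2 +/- without and with V617F, and 1 for each interaction. Ezh2 +/- without V617F had 5 without the sex term, 5 among females, 7 with the block and 5 without the 3 libraries. The granulocyte, monocyte and interferon lists were called higher among females and lower without the 3 libraries. Ezh2 +/- with V617F had 0 without the sex term, 0 among females and 4 with the block, and the interaction with Ezh2 +/- had 7 without the sex term. The r of 0.437 across genes was 0.283 with no filter, 0.341 among females, 0.539 for genes called in either and 0.505 without the 3 libraries.

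Leaving out 1 library gave 2096 to 3595 calls for Ezh2 -/- and 1 to 2 for Ezh2 +/- without V617F, 1954 to 5151 and 1 to 37 with it, 2518 to 3279 for V617F in Ezh2 +/+, 3197 to 6112 in Ezh2 -/- and 706 to 1893 in Ezh2 +/-, and 297 to 4633 and 0 to 0 for the interactions. Lists called were 9 to 12, 2 to 8, 9 to 13, 0 to 8, 7 to 10, 13 to 15, 11 to 13, 12 to 15 and 1 to 8 in the same order, and the r was 0.358 to 0.508.

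All changes of sign came with the lineage scores, and none was called after it. Some of these genes are members of the lists used as covariates, and the cause was not tested. For V617F in Ezh2 +/+ they were Camp -0.47, Elane -0.64, Ngp -0.31, Il2rb 0.67, Ccl5 1.28, Tcf7 0.18, Cd7 0.25, Ablim1 1.43, Hoxb2 -0.14, Hoxb5 -0.34, Hoxb3 -0.53, Ly6c2 -0.77, Cd3g 0.99, Cd3d 0.65, Il7r 0.76, Pim3 0.20, Ccl4 1.40, Ccl3 2.01, Nfkbia 0.04, Eda2r -0.30, Atf3 0.55, Ddit3 0.42 and Junb 0.34. For V617F in Ezh2 +/- they were Chil3 -1.42, Ccl5 1.47, Il2rb 1.05, Tcf7 0.49, Cd7 0.35, Hoxb2 -0.13, Cd22 0.11, Cd3g 0.94, Cd3d 0.80, Il7r 0.97, Satb1 0.05, Ccl3 1.96, Ccl4 1.89 and Ddit3 0.23.

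For V617F in Ezh2 -/- those reported here were Elane -1.08, Il2rb 0.12, Slc26a1 0.20, Trim2 0.54, Ezh1 -0.44, Rbbp7 0.25, Eed 0.19, Yaf2 0.10, Ring1 0.13, Prdm16 -1.16, Hoxb3 -0.98, Hoxb2 -0.36, Hoxb5 -1.01, Nfe2 -0.31, Gata2 -0.20, Aqp1 0.01, Epor 0.25, Alad 0.01, Slc25a38 0.20, Urod 0.09 and Ppox 0.15. The others were Ly6c2 -0.96, Cx3cr1 -0.48, Nkg7 -0.64, Cd28 0.17, Klrd1 0.27, Runx1 -0.04, Trim30a -0.16, Gbp3 -1.10, Cxcl10 0.07, Isg20 0.47, Mcm5 0.11, Mcm7 0.11, Tyms 0.22, Bax 0.06, Ei24 0.14, Ddit4 -0.21, Hspa8 0.23, Hsph1 0.55, Ddit3 0.46, Rplp1 0.12 and Rps2 0.08.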

Other observations

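With V617F in Ezh2 -/- MEPs (n = 6 against 4, edgeR), 10 of 22 immediate early and stress genes rose, 3 fell and 9 did not pass (12 and 4 adjusted over the list alone; camera adjusted p = 0.00451, 0.465 with an estimated correlation). Egr1, an early growth response factor, rose from 99.6 ± 20.6 to 609 ± 52.2 CPM (log2 2.52 ± 0.33, adjusted p = 2.08e-05), Egr2 by 2.0 ± 0.33 and Fos by 1.26 ± 0.25. The antiproliferative gene Btg2 rose by 1.30 ± 0.27, in the p53 target list, where 1 of 20 members rose and 5 fell. Of 8 stromal and endothelial genes 5 rose and 3 did not pass, by either adjustment, with Tie1 at 3.66 ± 0.65, the vascular receptor gene Kdr at 2.41 ± 0.49 and Emcn at 5.53 ± 1.15. The list's median was 1.73 (camera adjusted p = 0.0162 with the preset and 0.433 with an estimated correlation), and the call ended among female libraries only. Gata2 went from 106 ± 29.1 to 261 ± 29 CPM, and Il4 (2.65 ± 0.44) and Fcer1a (5.03 ± 0.96) of the mast cell list rose.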
